A study of Mus musculus with 10 samples.

How the data were processed

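RNA was sequenced from hematopoietic stem cells sorted from mouse bone marrow as CD48-negative, CD150-positive cells of the lineage-negative, Sca-1-positive, Kit-positive (LSK) gate. The mice were wild-type C57BL/6J animals given an intraperitoneal injection of DMSO, the solvent, or of tunicamycin at 2 mg per kg. Tunicamycin blocks the first step of N-linked glycosylation and is used to load the endoplasmic reticulum (ER) with unfolded protein. There were 5 libraries per group, 10 in all, grouped by the treatment in their titles. The labels' protocols give RNA extraction with a miRNeasy kit, reverse transcription and amplification by Geo-seq (a protocol for small cell numbers) and a Tn5-based library kit. They do not give the time between injection and sorting, the number of cells, or whether each library came from its own animal, so the p-values measure the spread between these samples.

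The authors deposited a single table of FPKM values, fragments scaled to the length of the gene model and the depth of the library, for 51670 mouse gene models. Per the submitters' processing notes, the tools included Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2, and the genome build was mm10. The role of each tool, the annotation and the versions of HTSeq and DESeq2 are not given in the sources used here. The FPKM sums of the libraries ranged from 436970 to 499251, so no scaling to a common sum had been applied. In 9 libraries the deposited FPKM values carry 4 decimals. In the library Tunicamycin replicate 1 every deposited value is a whole number, and that column was treated as a score on the FPKM scale without its decimals. Its genes expected at 5 to 20 FPKM from the other treated libraries lay 1.32 FPKM below expectation at the median, against -0.149 to 0.576 in those libraries. No source says whether it was rounded or truncated. Lost decimals move a value by less than 1 FPKM, so they alone do not account for this shift. On the second axis of a principal component analysis this library lay at 53.8, the other treated ones at -23.6 to 0.686. Lost decimals of low genes may contribute to that distance. By its shift at 5 to 20 FPKM, the library may differ from the others in more than its decimals. With whole numbers only, values of genes near 1 FPKM in that library are coarse.

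The table holds no read counts. Multiplied by gene length (merged exons in GENCODE release M21, the same build), low FPKM values of the other 9 libraries lay on steps of a fixed size: 84.5% to 96.1% of them were within 0.05 reads of a whole number. The step sizes correspond to about 18600000 reads in DMSO replicate 3 and up to about 60500000 in DMSO replicate 4, and to about 35500000 to 57700000 in the 4 treated libraries that could be read. A single read in a 2 kb gene was worth 0.00827 to 0.0268 FPKM. The depth of Tunicamycin replicate 1 could not be estimated. The steps rest on lengths from another annotation than the unnamed one of the authors, so no count test was run, and the planned test of counts did not apply.

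Gene identifiers were matched to symbols for 51389 of the 51670 models. Genes with FPKM of at least 1 in at least 5 of the 10 libraries were tested, 14727 in all. A gene under 1 FPKM in every DMSO library was tested only if all 5 treated libraries reached 1 FPKM. Such a gene was not tested where a treated library was left out. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), with the group as the only term and Benjamini-Hochberg adjustment, and a gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene given in the text comes from this limma fit. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds of mean FPKM are given where stated. Single values per library were compared by exact two-sided permutation tests over the 252 assignments of 5 and 5 libraries, whose smallest possible p is 0.00794. Data were simulated for this comparison over 14727 genes, with 50 genes changed at each size and noise independent between genes. There the fit recovered 22% of genes changed by 0.5, 86% by 1, 98% by 2 and 100% by 3 (log2 scale). Of its calls 4.38% were false. The simulation changed far fewer genes than were called in the real data and held no whole-number library. These rates need not hold for the real libraries, whose genes are not independent. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.

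Before the data were examined, 37 gene lists were fixed. For each, the members past the threshold were counted over all genes tested and adjusted over the list alone. The 36 lists with at least 5 tested members were also tested with limma's camera at a preset correlation of 0.01. Camera called 24 lists, 15 higher and 9 lower, and none of these calls held with an estimated correlation, where the adjusted p ranged from 0.371 to 0.944. Lists are therefore described by their counts and by a test chosen after the data were seen: the mean log2(FPKM + 1) of the list minus the mean of all tested genes, per library, with an exact two-sided permutation test and Benjamini-Hochberg adjustment over the 37 lists. This relative score differed for 29 lists, 20 higher and 9 lower in the treated libraries, and 24 of them reached the smallest p the design allows, an adjusted p of 0.0122. Genes of a list are not independent of each other. Of all tested genes 29.9% rose and 15.4% fell, the shares beside which the counts of a list stand. The groups did not overlap for 30.2% of tested genes, so a list reaches the smallest p easily. No random lists were scored for comparison.

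The genes named in the text were chosen by a rule with 5 parts: the members of the EMP and PMP22 family; 10 ER stress genes fixed in advance; the 10 largest rises and 10 largest falls among changed genes with no overlap between the groups and a mean of at least 5 FPKM in a group, leaving out models without a proper name; up to 4 members of each described list with the smallest p; and, for lists of other cell types, the most abundant members. The rule named 180 genes. The text gives examples from them, and the alternatives and the search for outlying samples covered all 180 and 8 genes chosen after their values were seen, which are marked as such. Positions are 1-based and come from GENCODE release M21 on GRCm38, the assembly that mm10 denotes.

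Alternatives changed the pseudocount, the filter on low values, the scaling between libraries, the variance model, the replicate block, the correlation of the list test and the set of libraries, leaving out each library in turn. After the data were seen, whole-number values in every library, the removal of libraries or a model term for Y-linked transcripts, and the removal of the library with the highest background in each group were added. Expression of Y-linked genes marked 2 DMSO libraries, replicates 3 and 5, and none of the treated ones, and the labels used here do not give the sex of the mice. Near-identical genes (alpha and beta globins, histones, ribosomal protein genes and their pseudogenes) share reads, and their single values are uncertain. No per-sample column was left out.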

Results

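The data describe gene expression in stem cells of the bone marrow from mice injected with DMSO (5 libraries) or tunicamycin (5 libraries). The series title asks about EMP1, epithelial membrane protein 1, in relation to ER stress in these cells, and the comparison of both groups shows how Emp1 and all other genes stood after a drug that causes ER stress. Between 13464 and 18378 gene models reached 1 FPKM per library. Libraries of one group correlated at 0.970 to 0.987 (DMSO) and 0.954 to 0.984 (tunicamycin) over the tested genes, and libraries of different groups at 0.886 to 0.944. Values below are mean FPKM ± SD over 5 libraries (n = 5 per group) unless stated otherwise, and changes are tunicamycin against DMSO.

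Emp1 rose in every treated library. Its level was 1.41 ± 0.461 FPKM after DMSO and 15.9 ± 1.38 FPKM after tunicamycin, an 11.3-fold difference of the means. The 5 treated libraries lay between 14.3 and 18 FPKM and the 5 DMSO libraries between 0.755 and 1.79 FPKM, so the groups did not overlap. The log2 change was 2.83 ± 0.14 (SE) with an adjusted p of 1.27e-07 in limma, and the exact two-sided permutation test gave the smallest p possible with n = 5 per group, 0.00794. Emp1 (ENSMUSG00000030208) is a protein-coding gene on chromosome 6, positions 135362545 to 135383173, plus strand. DMSO replicates 3 and 5 held Y-linked transcripts (sums of 61.3 and 51.6 FPKM) and little Xist (0.15 and 0.0654 FPKM), while the other 8 libraries, all treated ones included, had 28.2 to 35.6 FPKM of Xist. With those 2 DMSO libraries left out, so that only libraries with Xist were compared, the log2 change of Emp1 was 2.84 ± 0.17 (SE). Markers of macrophages (16 of 18), endothelial cells (14 of 14) and stromal cells (10 of 14) rose in the same libraries. With those 2 DMSO libraries left out, 12, 9 and 7 of them rose.

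Of the 4 members of the EMP and PMP22 family of small membrane proteins, 3 rose, and the same 3 rose when adjusted over the list alone. Pmp22, a component of peripheral myelin, went from 1.11 ± 0.306 to 10.9 ± 2.82 FPKM (log2 change 2.47, adjusted p 2.46e-06). Emp2 stayed low, at 0.338 ± 0.156 FPKM after DMSO and 2.13 ± 0.853 FPKM after tunicamycin, with a log2 change of 1.19 (adjusted p 0.000589). No DMSO library reached 1 FPKM of Emp2, and Tunicamycin replicate 1 held exactly 1 FPKM. With any 1 treated library left out Emp2 was not tested, and 2 of the 3 tested members rose. Emp3 was by far the most abundant member and did not pass the test, with 194 ± 18.9 FPKM after DMSO and 187 ± 44.1 FPKM after tunicamycin (log2 change -0.08, adjusted p 0.728), and the sign of its small difference turned with quantile normalization, with TPM scaling and without Tunicamycin replicate 1. With equal medians Emp3 passed as lower.

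**Figure D1:**
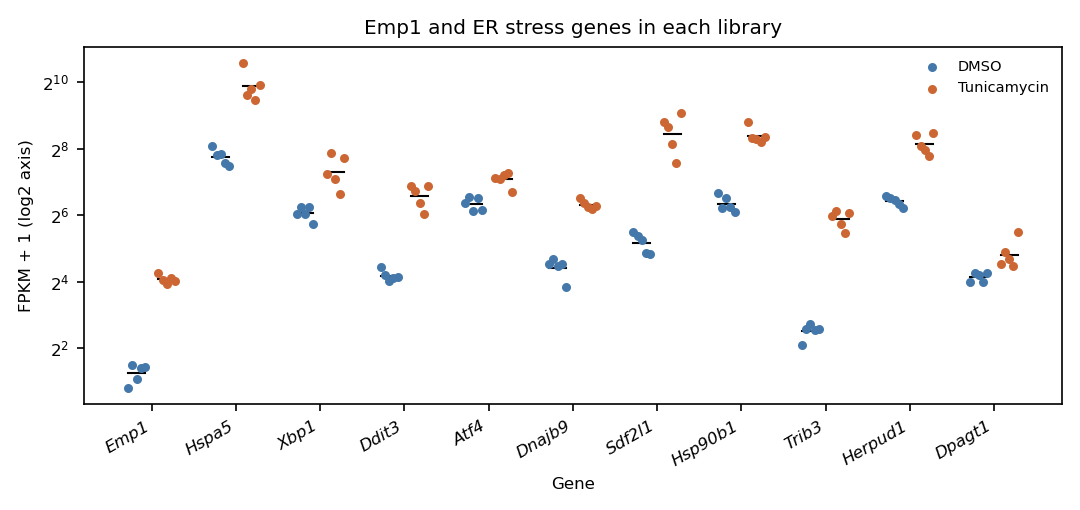
FPKM + 1 of Emp1 and 10 ER stress genes on a log2 axis, one point per library (5 DMSO in blue, 5 tunicamycin in orange), with black lines at the means of log2(FPKM + 1). Emp1 sits between 14.3 and 18 FPKM in the treated libraries and below 2 FPKM in the DMSO libraries.

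Genes of the unfolded protein response rose together. The 10 ER stress genes fixed in advance all rose. Hspa5, which encodes the main ER chaperone BiP, went from 217 ± 37.7 to 969 ± 321 FPKM (log2 change 2.12 ± 0.20 SE). Ddit3, which encodes the stress factor CHOP, went from 17.3 ± 2.02 to 97.3 ± 22.9 FPKM, and its target Trib3 from 4.74 ± 0.856 to 58.4 ± 10.8 FPKM. Sdf2l1 rose 10.4-fold and the chaperone Hsp90b1 4.15-fold in mean FPKM. Xbp1, the factor activated by the sensor IRE1, rose by 1.25 on the log2 scale and its target Dnajb9 by 1.90. Smaller rises were those of Atf4 (0.74) and of Dpagt1 (0.68, adjusted p 0.00722), which encodes the enzyme that tunicamycin inhibits.

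By list, 11 of the 13 tested sensors and transcription factors of the unfolded protein response rose and 0 fell, among them Atf6 (0.72 on the log2 scale) and Ddit3 (2.40). Of 30 ER chaperones and folding enzymes 22 rose and 0 fell, led by Pdia4 (51.7 ± 6.14 to 302 ± 62.5 FPKM) and Creld2 (38.4 ± 5.99 to 235 ± 48.6 FPKM), and 1 fell without DMSO replicate 2. The mean log2(FPKM + 1) of this list was 4.68 ± 0.08 (SD, n = 5) after DMSO and 5.77 ± 0.23 (SD, n = 5) after tunicamycin, a difference of 1.10 with an exact permutation p of 0.00794. Of 25 genes of ER-associated degradation, which removes misfolded proteins, 14 rose and 2 fell, or 1 without DMSO replicate 1, 4 or 5 or Tunicamycin replicate 2, 3 or 4. Derl3 had the smallest p of all named genes and went from 0.605 ± 0.21 to 61.7 ± 12.8 FPKM (chromosome 10, positions 75893413 to 75895941). Sel1l and Herpud1 in the same list rose by 1.78 and 1.72 on the log2 scale, and Os9 by 0.91. Among 34 genes of ER translocation and vesicle transport 12 rose, such as Mcfd2 (1.48) and Sec24d (1.21), and 2 fell (12 and 0 adjusted over the list alone). Without Tunicamycin replicate 2 the translocation rises were 7, and in libraries with Xist alone 6. The falls were 4 without Tunicamycin replicate 5 and 0 or 1 without any other library. The N-glycan synthesis list moved little, with 7 of 39 members higher and 3 lower (6 and 3 adjusted over the list alone, and 4 higher in libraries with Xist alone). Alg12 rose by 0.78 and Alg8 had a log2 change of -0.68. With each library set to the same median, these last lists turned, with 5 higher and 10 lower translocation genes and 2 higher and 12 lower N-glycan genes. With TPM scaling 16 translocation genes were higher and 0 lower, and 12 N-glycan genes were higher and 3 lower. Without Tunicamycin replicate 1, 10 N-glycan genes rose and 4 fell. Of 9 genes known as substrates of IRE1-dependent mRNA decay 4 rose and 0 fell. One of those that rose is Pmp22, and Sparc and Pdgfrb also belong to the stromal list described below. In this and the following lists, counts adjusted over the list alone were equal to those over all genes tested unless both are given.

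The targets of ATF4 and CHOP were split. Of 28 tested members 17 rose and 5 fell. With any 1 treated library left out 24 were tested, of which 12 or 13 rose and 5 or 6 fell. Gdf15, a secreted stress factor, went from 3.07 ± 1.45 to 82.1 ± 43.6 FPKM, Chac1, which degrades glutathione, from 0.471 ± 0.289 to 6.34 ± 0.849 FPKM, and Slc3a2, the heavy chain of amino acid transporters, from 77.8 ± 10.1 to 259.8 ± 52.0 FPKM. Asns and Psat1, enzymes of asparagine and serine synthesis, fell, with log2 changes of -1.52 and -0.57 (both chosen after their values were seen). Cytosolic aminoacyl-tRNA synthetases, several of which ATF4 is also known to activate, had 9 members lower and 1 higher out of 20 (0 higher without DMSO replicate 4 or Tunicamycin replicate 2). The log2 changes of Hars, Rars and Kars were -1.15, -0.75 and -0.82. The relative score rose for the ATF4 and CHOP targets (by 0.76) and fell for the synthetases (-0.45), with exact permutation p-values of 0.00794 and 0.0238 (adjusted 0.0122 and 0.0304). In the cell death and p53 lists, 12 of 25 BCL2 family and caspase genes rose and 2 fell, and 11 of 24 p53 targets rose and 3 fell. Of all tested genes 29.9% rose and 15.4% fell, against 48% and 8% of the first list and 45.8% and 12.5% of the second. With any 1 treated library left out, 22 members of the first list were tested and 8 to 14 rose. Of the members of these lists 4 and 7 also stand in another list. Macrophage markers (16 of 18) and immediate early genes (16 of 16) rose in the same libraries. Bbc3, which encodes the death-promoting protein PUMA, rose 4.49-fold in mean FPKM and the survival gene Bcl2l1 rose 2.12-fold. The p53 targets Btg2 and Ddit4 rose by 2.16 and 2.41 on the log2 scale.

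Genes of DNA replication and division fell. All 40 tested members of the G1/S and DNA replication list were lower, with a median log2 change of -1.34. Uhrf1 went from 65.6 ± 8.73 to 19.7 ± 3.01 FPKM, and the replication factors Mcm5 and Mcm10 had log2 changes of -1.73 and -1.74. In the G2/M and mitosis list 38 of 40 members fell, for example Cdk1 (-1.29) and Top2a (-1.39), and 1 rose. That gene was Pttg1, securin (log2 change 0.47, adjusted p 0.0203; chosen after its value was seen), whose call was lost with equal medians, with no filter on low values, without Tunicamycin replicate 2 and in libraries with Xist alone. Among 15 cyclins, kinases and inhibitors of G0 and G1, 5 rose and 2 fell, with 3 rises without DMSO replicate 5, without Tunicamycin replicate 2 or in libraries with Xist alone. Cdk4, which drives G1, was lower (287 ± 19.7 after DMSO, 142 ± 17.0 FPKM after tunicamycin), while the inhibitors Cdkn1a (p21) and Cdkn2d (p19) rose by 1.99 and 1.05 on the log2 scale. The relative score of the G1/S list differed by -1.51 and that of the G2/M list by -1.10, each with an exact permutation p of 0.00794 (adjusted 0.0122). The mean of 4 erythroid progenitor genes, not a fixed list, was lower in the same libraries, as described below. The fixed erythroid marker list split, 7 higher and 7 lower of 15.

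Genes that mark stem cells were mostly higher. Of 43 genes of the HSC identity list 29 rose and 1 fell (33 and 1 adjusted over the list alone), and 17 rose with equal-median scaling and 21 in libraries with Xist alone. Sult1a1 went from 27.9 ± 5.12 to 151 ± 15.9 FPKM, Egr1 from 29.5 ± 8.77 to 263 ± 71.7 FPKM, Gata2 from 62.0 ± 14.6 to 132 ± 15.6 FPKM and the surface protein gene Esam from 68.7 ± 6.36 to 130.4 ± 19.3 FPKM. Endothelial markers (14 of 14), megakaryocyte markers (12 of 16) and immediate early genes (16 of 16) rose in the same libraries. Of the stem cell genes 3 also stand in another list, Egr1 among them as an immediate early gene, and Esam is also expressed by endothelial cells. The member that fell was Gfi1b, a transcriptional repressor that erythroid and megakaryocyte development requires (-0.75 on the log2 scale, adjusted p 0.00738, chosen after its value was seen). Of 24 genes of multipotent and lineage-primed progenitors 8 rose and 4 fell (9 and 4 adjusted over the list alone). Its median log2 change was 0.43 and its relative score differed by -0.06, with an exact permutation p of 0.786. Car1 (carbonic anhydrase 1) and Klf1 (an erythroid transcription factor) fell, by log2 changes of -3.18 and -2.26, and Cd48 and Irf8 rose, by 1.23 and 1.84.

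Signalling and inflammatory genes rose. All 16 tested immediate early genes were higher, with Junb at 65.0 ± 21.7 FPKM after DMSO and 527 ± 111 FPKM after tunicamycin and log2 changes of 1.90 for Dusp1 and 2.18 for Ier2. These genes also respond to handling of cells during isolation, and the list had been fixed for that reason. Of 25 NF-kB and inflammatory genes 22 rose and 0 fell (23 and 0 adjusted over the list alone). Socs3, a feedback inhibitor of cytokine signals, went from 4.61 ± 0.637 to 44.2 ± 11.5 FPKM and Cd83 from 2.72 ± 0.717 to 12.6 ± 3.28 FPKM. Of 36 interferon-stimulated genes 27 rose and 0 fell (29 and 1 adjusted over the list alone), with Rsad2 up by 1.57 and Ifi44 by 0.93 on the log2 scale. Without DMSO replicate 3 or Tunicamycin replicate 1, 1 fell. Macrophage markers rose in the same libraries (16 of 18). With equal-median scaling 15 interferon-stimulated genes rose and 2 fell, and 17 rose in libraries with Xist alone.

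Genes of protein synthesis and mitochondrial energy production fell. Abundant genes also fell as a class: of those with at least 100 mean FPKM 138 rose and 286 fell, with a median log2 change of -0.39. The median log2 changes of the ribosomal protein, oxidative phosphorylation and proteasome lists were -0.86, -0.57 and -0.55. How much of these falls goes with abundance was not tested. Cell-cycle genes fell in the same libraries. Of 78 cytosolic ribosomal protein genes 76 were lower and 0 higher (77 lower adjusted over the list alone). Rplp2 had a log2 change of -1.16. Of 68 nuclear genes of oxidative phosphorylation 50 fell and 0 rose (51 lower adjusted over the list alone). Atp5b, a subunit of the ATP synthase, was at 1483 ± 192 FPKM after DMSO and 678 ± 129.7 FPKM after tunicamycin, and Cycs, cytochrome c, had a log2 change of -1.16. Of the 13 genes encoded in the mitochondrial genome 10 fell (11 adjusted over the list alone), and the share of the FPKM sum in mitochondrial transcripts was 9.75 ± 1.45% (SD, n = 5) after DMSO and 5.74 ± 1.89% (SD, n = 5) after tunicamycin. With quantile normalization 5 of these genes fell, and in libraries with Xist alone 6. The list had been fixed as a measure of RNA quality. Tunicamycin replicate 5 had the lowest mitochondrial share, 2.88%. It also had the lowest share of an rRNA gene model, 2.59%, against 14.7% in Tunicamycin replicate 1. Without Tunicamycin replicate 5, 10 of the 13 genes fell. Whether RNA quality accounts for their fall was not tested. Proteasome subunits fell in 26 of 33 cases, such as Psmd1 (-0.73) and Psma1 (-0.66), and 11 of 18 cytosolic and mitochondrial heat shock genes fell while 3 rose (5 without Tunicamycin replicate 1). Hsp90aa1, the inducible cytosolic chaperone, went from 497 ± 108 to 152 ± 17.6 FPKM and Hspe1 had a log2 change of -1.39. In contrast, 21 of 31 autophagy and lysosome genes rose and 0 fell (22 and 0 adjusted over the list alone). The lysosomal protease Ctsd was at 214 ± 26.5 FPKM after DMSO and 940.1 ± 385 FPKM after tunicamycin, and the autophagy receptor Sqstm1 at 94.8 ± 6.79 and 312 ± 43.3 FPKM. Macrophage markers rose in the same libraries (16 of 18). Ctsd was highest in Tunicamycin replicate 1, at 1620.0 FPKM, and so were the macrophage markers Vcam1, Cd68 and C1qb, at 1172, 475 and 1114 FPKM. NRF2 and antioxidant genes went both ways, with 9 higher (Cat, 1.10; Ftl1, 1.27) and 9 lower (Nqo1, -1.36) out of 24.

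**Figure D2:**
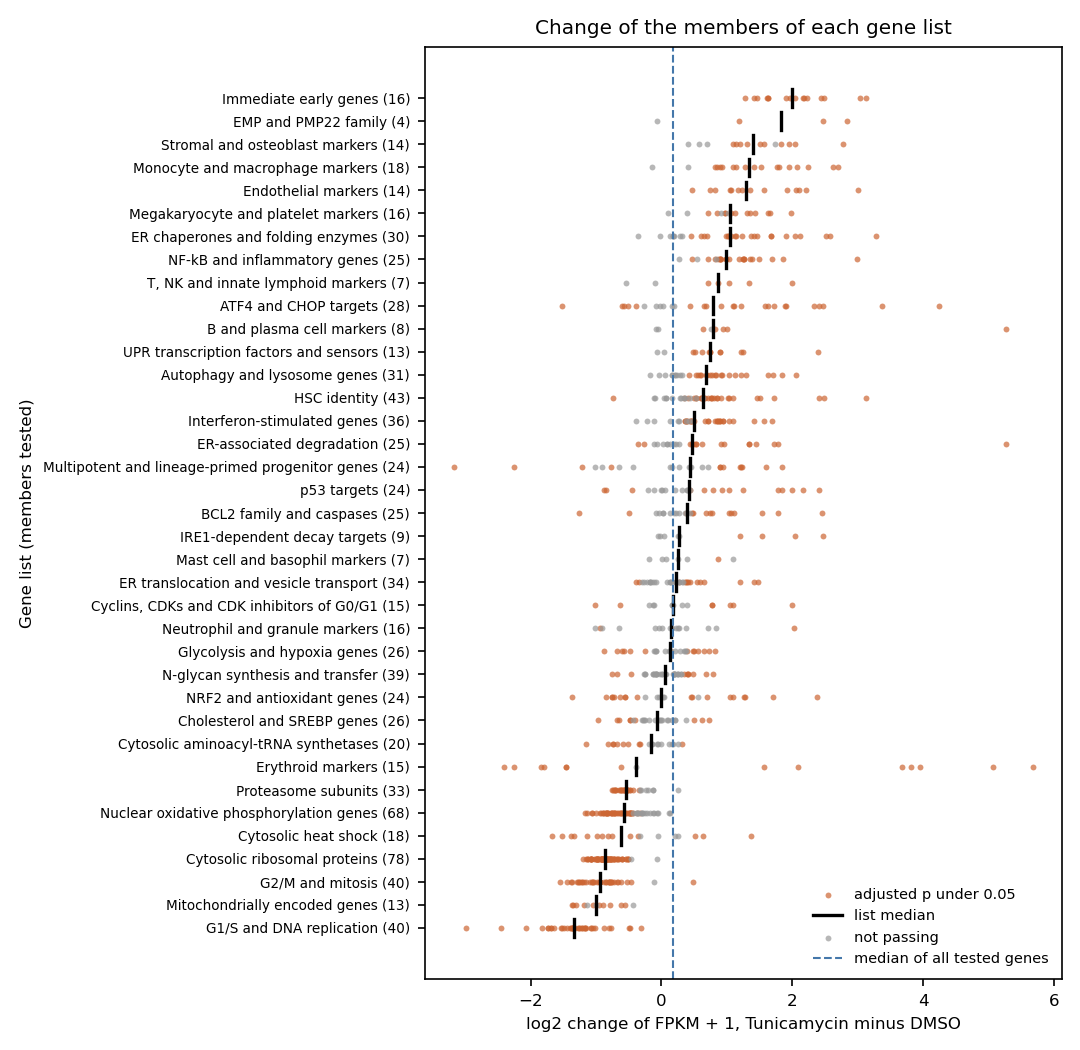
Log2 change of FPKM + 1 (tunicamycin minus DMSO, x axis) of the tested members of each of the 37 gene lists (y axis, number of members in brackets). Orange points passed an adjusted p of 0.05, grey points did not, black bars are list medians and the dashed line is the median of all tested genes, 0.18. Immediate early genes stand highest by median and the G1/S and DNA replication list lowest.

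The largest rises by the rule were those of the globins Hbb-bs, Hba-a2 and Hbb-bt, Derl3, Ccn2, Ccn1, Gdf15, Alas2, Ms4a6d and Ptx3. Hbb-bs, an adult beta globin, was at 58.1 ± 32.8 FPKM after DMSO and 2782 ± 1066 FPKM after tunicamycin. Alas2, the first enzyme of heme synthesis in erythroid cells, went from 3.19 ± 1.36 to 57.3 ± 14.6 FPKM. Ccn2 and Ccn1, matrix proteins and YAP targets, rose by 4.72 and 4.41 on the log2 scale, Ms4a6d by 3.81 and the pentraxin Ptx3 by 3.79. The globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt are near-identical in pairs, and their single values are uncertain. The largest falls were those of Cldn13, Car1, Ccne1, Rhd, Aldh1a7, Slc38a5, Hist1h2ak, Hist1h2ab, Rrm2 and Ermap. Cldn13 fell from 161 ± 65.2 to 18.7 ± 15.9 FPKM, Car1 from 2329 ± 889 to 300.3 ± 256 FPKM and Rhd, a blood group antigen gene, from 156 ± 51.4 to 21.6 ± 13.8 FPKM. Ccne1, the cyclin of S phase entry, had a log2 change of -2.99 and Rrm2, a subunit of ribonucleotide reductase, of -2.45. The histone genes Hist1h2ak and Hist1h2ab belong to a family of near-identical copies.

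Across all 14727 genes, 6664 changed, 4403 higher and 2261 lower, and 7725 had an unadjusted p under 0.05. By at least 1 on the log2 scale, 1019 rose and 454 fell. The groups did not overlap for 4443 genes, 30.2% of those tested, where chance gives 0.794%. The median log2 change of all genes was 0.18, and with other scalings the balance of calls moved. Quantile normalization gave 3425 higher and 3767 lower, equal medians 3037 higher and 3972 lower, and TPM scaling 5481 higher and 1693 lower. In libraries with Xist alone (3 DMSO and 5 tunicamycin libraries) 4744 genes changed, of which 4659 were called in the same direction with all 10 libraries. Left out alone, the whole-number library Tunicamycin replicate 1 moved the count to 7979.

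Markers of other bone marrow cells also differed between the groups, although the sort gate excludes mature cells of the blood lineages. Of 18 monocyte and macrophage markers 16 rose and 0 fell (12 rose in libraries with Xist alone and 13 with equal medians). Cd68 went from 51.3 ± 12.1 to 345 ± 107 FPKM, Vcam1 from 116 ± 33.0 to 724 ± 268 FPKM, C1qb from 245 ± 85.3 to 609 ± 293 FPKM, C1qc from 95.6 ± 42.5 to 410.2 ± 183 FPKM and Lyz2 from 341 ± 56.0 to 613 ± 82.7 FPKM. All 14 endothelial markers rose (9 in libraries with Xist alone), among them Fabp4 (7.60 ± 5.81 to 61.4 ± 39.1 FPKM), Eng (85.8 ± 13.1 to 156 ± 51.4 FPKM), Pecam1 (21.4 ± 3.71 to 46.0 ± 8.95 FPKM) and Cldn5 (7.44 ± 3.65 to 40.1 ± 24.2 FPKM). Of 14 stromal and osteoblast markers 10 rose and 0 fell (12 and 0 adjusted over the list alone). With all libraries rounded to whole FPKM 6 of 16 rose, and 7 of 14 in libraries with Xist alone. Sparc went from 43.2 ± 28.2 to 149 ± 63.7 FPKM, Bglap, raised mostly in 1 treated library, had a log2 change of 1.95, and Spp1 went from 11.3 ± 8.50 to 84.6 ± 67.0 FPKM. Megakaryocyte and platelet markers rose in 12 of 16 cases (13 adjusted over the list alone), with Pf4 at 303 ± 130.2 and 766 ± 219 FPKM, Ppbp, which did not pass, at 67.5 ± 53.4 and 58.0 ± 23.4 FPKM (log2 change 0.09, opposite in sign to the difference of these means), and log2 changes of 1.35 for Itga2b and 1.98 for Selp. The DMSO libraries already held FPKM of at least 1 in every library for 18 of the macrophage, 10 of the endothelial, 9 of the stromal and 14 of the megakaryocyte markers. Such markers may also be expressed by the sorted cells, as may be so for Eng, at 85.8 FPKM after DMSO.

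Neutrophil and granule markers had 1 member higher (Ifitm6, 2.02) and 1 lower (Fcnb, -0.94) out of 16 (1 and 0 adjusted over the list alone). Without DMSO replicate 2 or Tunicamycin replicate 1, 2 rose. The fall was lost without DMSO replicate 2 or 3 or Tunicamycin replicate 1, 3 or 4, and 2 fell without DMSO replicate 5. The most abundant members did not pass, with S100a8 at 133 ± 91.1 and 173 ± 198 FPKM, Elane at 358 ± 303 and 152 ± 97.2 FPKM, Mpo at 281 ± 243 and 119 ± 58.1 FPKM and Prtn3 at 229 ± 103 and 359.7 ± 96.9 FPKM. Prtn3 passed as higher with quantile normalization, TPM scaling or array weights and without DMSO replicate 2 or Tunicamycin replicate 1. Mpo passed as lower with array weights, and both Mpo and Elane without DMSO replicate 5. Of 7 mast cell and basophil markers 1 rose (Gzmb, 0.87), and Cpa3, which passed as higher with array weights, was at 6.13 ± 2.01 and 8.15 ± 1.91 FPKM. Prss34, Hdc and Mcpt8 in this list did not pass, with log2 changes of 0.0012, 0.06 and -0.20, and the sign of each turned in at least 1 alternative. Of 8 B and plasma cell markers 5 rose (6 adjusted over the list alone, and 3 without Tunicamycin replicate 2, 3, 4 or 5 or in libraries with Xist alone), including Derl3, which also stands in the ER-associated degradation list, Ebf1 (adjusted p 0.000709) and Cd79b (0.64), while Jchain did not pass (-0.05, adjusted p 0.956). Of 7 T, NK and innate lymphoid markers 5 rose and 0 fell (5 and 1 adjusted over the list alone, and 1 fell without DMSO replicate 5 or Tunicamycin replicate 5), with Cd4 at 3.83 ± 1.35 and 17.9 ± 3.55 FPKM and Lat up by 1.04, while Lck and Nkg7 did not pass over all genes tested (-0.11 and -0.54). Nkg7 passed as lower with equal medians or array weights and without DMSO replicate 5 or Tunicamycin replicate 5. The other markers fixed for these lists were too low to be tested: 17 B and plasma cell and 22 T, NK and innate lymphoid markers were listed. Of the tested ones, 3 and 5 held at least 1 FPKM in every DMSO library. Without Tunicamycin replicate 2, 3, 4 or 5, only 6 B and plasma cell markers were tested. Erythroid markers split, 7 higher and 7 lower of 15 (7 and 8 adjusted over the list alone). The globins and Alas2 rose while Car2 went from 2986 ± 750.1 to 846 ± 133 FPKM and Ermap had a log2 change of -2.41. The median of this list was -0.39, its mean 0.91 and its relative score 0.74, so these measures differ in sign.

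**Figure D3:**
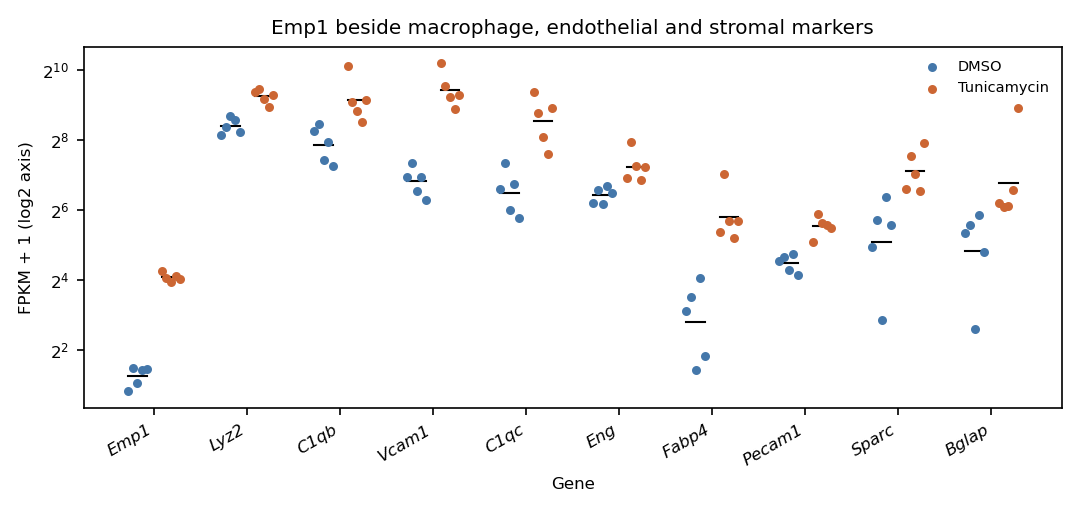
FPKM + 1 of Emp1 beside abundant markers of macrophages (Lyz2, C1qb, Vcam1, C1qc), endothelial cells (Eng, Fabp4, Pecam1) and stromal cells (Sparc, Bglap) on a log2 axis, one point per library (5 DMSO in blue, 5 tunicamycin in orange), with black lines at the means of log2(FPKM + 1). The treated libraries differ more from each other in the marker genes than in Emp1, which lies between 14.3 and 18 FPKM in them.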

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

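The tests of explanations in this part were chosen after the results were seen. In 460 groups of 5 values (named genes, list scores and library measures), 31 had a sample far from the other 4, 12 among DMSO and 19 among treated libraries, where chance alone flags about 1 in 20, so single entries carry little weight.

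Tunicamycin replicate 1, the whole-number library, stood apart for 9 genes. It had 440.0 FPKM of Hsp90b1 (others 291 to 325), 47 of Cldn13 (10.7 to 12.9), 12 of Ccne1 (4.51 to 5.97), 46 of Rhd (13.0 to 18.7) and 69 of Hars (47.5 to 50.1). It also had 25 FPKM of Uhrf1 (17.9 to 19.1), 1620.0 of Ctsd (702 to 861), 3 of Fas (4.29 to 4.89) and 1 of Klrb1c (4.14 to 5.85). Tunicamycin replicate 2 had 9.60 FPKM of Cdk1 (12.1 to 13), 25.8 of Ifitm6 (10.4 to 12.7) and 130.4 of Fabp4 (35.6 to 50.8). The mast cell genes Tpsb2 and Prss34 were at 19.3 FPKM (0.634 to 2) and 24.6 FPKM (0.567 to 2) in that library, and its mast cell and basophil score was 2.97 (1.46 to 1.87). Tunicamycin replicate 4 had 6.10 FPKM of Pmp22 (11.2 to 13.5) and 63.6 of Os9 (73.7 to 76). Tunicamycin replicate 5 had 487 FPKM of Bglap (67.6 to 94.0) and a stromal and osteoblast score of 5.11 (3.98 to 4.16). Among the DMSO libraries, replicate 3 had 0.213 FPKM of Ccn1 (2.78 to 3.37) and 0.983 of Chac1 (0.283 to 0.401). Its NRF2 and antioxidant score was 5.76 (5.85 to 5.87), its ribosomal protein score 8.62 (8.99 to 9.09), and 15841 gene models reached 1 FPKM (13464 to 13955). DMSO replicate 2 had 6.07 FPKM of Ddit4 (2.62 to 3.38), 87.2 of Gata2 (51.8 to 60.1) and 3.49 of Creb3l2 (2.81 to 2.95). DMSO replicate 1 had 23.9 FPKM of Scd2 (36.5 to 42.4) and 72.9 of Ly6a (93.4 to 100.7), and replicate 5 had 13.4 of Dnajb9 (21.2 to 24.6) and 0.201 of Cd79a (1.10 to 1.56).

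The rise of Emp1 was set against RNA of other cells that rose in the same libraries. If other cells of an unchanged profile had brought Emp1, its excess over the DMSO mean would vary between the treated libraries as that of their abundant transcripts does. The highest excess of Emp1 was 1.29 times the lowest, against 3.87 times for Lyz2, C1qb, Vcam1 and C1qc summed, 4.34 times for Eng, Fabp4, Pecam1 and Plvap summed, and 7.77 times for Bglap, Sparc, Col1a1 and Spp1 summed. Eng and Pecam1 were already well expressed in the DMSO libraries, so their excess need not come from endothelial cells. One library carried much of each of these values: the macrophage sum fell to 2.24 times without Tunicamycin replicate 1 (Emp1 1.16), the endothelial sum to 2.17 times without replicate 2 (Emp1 1.29) and the stromal sum to 1.78 times without replicate 5 (Emp1 1.29), below the bound of 1.94 set at 1.5 times Emp1. The markers did not keep one profile, since the ratio of 2 of them varied by up to 3.22 times among the macrophage and 13.8 times among the endothelial markers, so RNA from each of the 3 cell types cannot be told apart from a rise within the sorted stem cells, which stays open as a hypothesis with the treatment as the biological difference.

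The rise of macrophage, endothelial and stromal markers was weighed next. A lower share of stem cell RNA would raise markers of all other cell types alike only if the other cells kept their proportions. The macrophage score rose by 1.32 more than the neutrophil score (exact permutation p 0.0317, n = 5 per group). The stem cell identity list rose against all genes. Relative scores were also higher for megakaryocyte (0.92), B and plasma cell (0.99) and T, NK and innate lymphoid markers (0.59). For neutrophil and mast cell markers they differed by -0.09 and 0.18 and did not pass. The B and plasma cell list includes Derl3, a gene of ER-associated degradation, which alone rose by 5.27 on the log2 scale. The mean log2 change of that list was 1.16 and its median 0.79. Other cells need not come in equal shares, and 3 stem cell genes stand in another list, so this explanation cannot be excluded. Unspecific reads do not reach this size, since the median of 46 markers rose by 13.0 FPKM, 190 times the rise of 0.0684 FPKM in the mean of 1396 olfactory receptor models, or, without the whole-number library, which cannot show values so low, by 11.6 FPKM, 108 times a rise of 0.108 FPKM. More RNA from unchanged macrophages would raise the 3 chains of C1q by one factor, while the log2 ratio of C1qb to C1qc differed by -0.79 (exact permutation p 0.00794, n = 5 per group, adjusted 0.0119 over 3 ratios) and C1qa, chosen after its values were seen, went from 109 ± 48.4 to 395 ± 197 FPKM. Since all 3 chains rose, macrophage RNA that changed with the treatment cannot be told apart from expression in the sorted cells, because both follow the groups.

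The fall of cell-cycle genes came with a lower score of 4 erythroid progenitor genes, which is not one of the fixed lists. The fixed erythroid marker list split, 7 higher and 7 lower of 15. The progenitor score, the mean log2(FPKM + 1) of Gata1, Klf1, Epor and Car1, was 7.66 ± 0.42 (SD, n = 5) after DMSO. After tunicamycin this score was 5.81 ± 0.57 (SD, n = 5). If fewer erythroid-primed cells were the whole cause, the G1/S difference of -1.34 ± 0.12 (SE) would vanish with this score in the model, and it was -0.89 ± 0.21 (SE, 95% interval -1.39 to -0.38). The scores of the groups do not overlap (lowest DMSO 7.21, highest tunicamycin 6.78), so this estimate extrapolates, and fewer erythroid-primed cells cannot be told apart from a fall within the other sorted cells. The scaling of the libraries is argued against, since the smallest fall of the G1/S median under 3 other scalings was -1.26. A treatment effect on cycling itself stays open as an untested hypothesis.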

How the results depend on the processing

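Whole-number values in every library, the libraries or term for Y-linked transcripts and the library of highest background were added after the data were seen, and the other alternatives were chosen before the data were examined. Emp1 was higher and past the threshold under all 15 other settings (log2 change 2.62 to 3.56) and with each of the 10 libraries left out in turn (2.73 to 2.89), with adjusted p-values up to 1.40e-05 in limma. The ER chaperone score stayed higher by 0.85 to 1.25 under 12 other settings and by 1.03 to 1.18 with each of the 10 libraries left out in turn. The count of changed genes ranged from 4672 to 9229 under 15 other settings and from 5332 to 7979 with each of the 10 libraries left out in turn, with 3294 to 5841 higher and 1891 to 2510 lower in the latter. The count of higher genes fell to 2824 at a mean FPKM of at least 5, where 8564 genes were tested. The count of lower genes rose to 3767 with quantile normalization and to 3972 with equal medians, which set the median of all genes near 0. Lists called by camera were 20 to 24 with each of the 10 libraries left out in turn and 0 with an estimated correlation. For 187 named genes apart from Emp1 under 25 alternatives, 4488 of 4599 values kept their direction and side of the threshold, 37 lost their call, 24 gained one and 50 reversed. A gene that was not tested under an alternative, such as Emp2 without a treated library, gave no value there and is not among these counts. Genes that reversed had not passed the test with all libraries, and the cause was not tested. With a term for Y-linked transcripts, Ppbp was at -0.56, Jchain at 0.15 and Kit at -0.0140. With all libraries truncated to whole FPKM, Jchain was at 0.0186. With array weights, Ppbp was at -0.13, S100a8 at -0.53, Jchain at 0.79, Hdc at -0.10, Prss34 at -0.35 and Kit at -0.0331. With equal medians, Ppbp was at -0.16, S100a8 at -0.13, Hdc at -0.13, Prss34 at -0.16 and Kit at -0.19. With a pseudocount of 0.01, Prss34 was at -0.0412. With a pseudocount of 0.1, Prss34 was at -0.0387. With quantile normalization, Emp3 was at 0.00206, Hdc at -0.21 and Prss34 at -0.28. With TPM scaling, Emp3 was at 0.0517, Jchain at 0.0197 and Lck at 0.00789. Without the 2 DMSO libraries with Y-linked transcripts, Ppbp was at -0.56, Jchain at 0.15 and Kit at -0.0140. Without the library of highest background in each group, Ppbp was at -0.43, Jchain at 0.66 and Mcpt8 at 0.19. With each of the 10 libraries left out in turn, the log2 change ranged from -0.40 to 0.44 for S100a8, -0.42 to 0.35 for Jchain, -0.72 to 0.47 for Prss34, -0.38 to 0.49 for Ppbp, -0.65 to 0.0452 for Mcpt8, -0.14 to 0.23 for Hdc, -0.18 to 0.0577 for Emp3, -0.27 to 0.0219 for Lck and -0.0266 to 0.19 for Kit. For the lists, the median relative to all genes kept its direction and side of the camera threshold in 833 of 898 values, with 31 calls lost, 7 gained and 27 reversed, all in lists that had not passed with all libraries. The cause was not tested. With a term for Y-linked transcripts, Neutrophil and granule markers was at 0.31. With all libraries rounded to whole FPKM, Cyclins, CDKs and CDK inhibitors of G0/G1 was at -0.0419. With all libraries truncated to whole FPKM, Cyclins, CDKs and CDK inhibitors of G0/G1 was at -0.0340 and Mast cell and basophil markers at -0.0340. With array weights, ER translocation and vesicle transport was at -0.0470 and IRE1-dependent decay targets at -0.0743. At a mean FPKM of at least 5, Erythroid markers was at 0.34. With no filter on low values, Glycolysis and hypoxia genes was at 0.0704 and Neutrophil and granule markers at 0.0488. With quantile normalization, Glycolysis and hypoxia genes was at 0.0529 and Neutrophil and granule markers at 0.0209. Without the 2 DMSO libraries with Y-linked transcripts, Neutrophil and granule markers was at 0.25. Without the library of highest background in each group, Neutrophil and granule markers was at 0.32. With each of the 10 libraries left out in turn, this relative median ranged from -0.0608 to 0.00321 for Glycolysis and hypoxia genes, -0.0188 to 0.11 for Cyclins, CDKs and CDK inhibitors of G0/G1, -0.53 to 0.25 for Neutrophil and granule markers, -0.21 to 0.28 for Mast cell and basophil markers and -0.00829 to 0.12 for ER translocation and vesicle transport. At whole FPKM, 6143 genes changed with rounding and 7030 with truncation. Without the library of highest background in each group 5220 changed, and with a term for Y-linked transcripts 5180.

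The replicate numbers 1 to 5 are shared by both groups and were checked for pairing. Deviations of same-numbered libraries correlated at 0.25, 0.23, 0.085, 0.074 and 0.021 across genes, all positive but not all above 0.1. Of the 10 libraries 5 matched their own number best. These values do not settle whether the numbers pair the samples, and the labels do not say so. Pairing stays open, and the main test left it out. With the replicate block 6801 genes changed, 4553 higher and 2248 lower, the Emp1 change was 2.83 and the list count 24. The ER chaperone score differed by 1.10 with an exact paired p of 0.0625 in the block fit, the smallest that 5 pairs allow. Depth limits low genes: a read in a 2 kb gene was worth up to 0.0268 FPKM, and the whole-number library does not resolve values below 1 FPKM. The planned test of counts was not run, since the table holds none.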

Other observations

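The surface markers of the sort gate differed in transcript level between the groups, apart from Kit. Of these genes Slamf1, Ly6a and Kit were chosen after their values were seen. Cd48, whose protein was selected against, was at 26.4 ± 7.52 FPKM after DMSO and 62.1 ± 9.25 FPKM after tunicamycin (log2 change 1.23, adjusted p 0.000163 in limma). Slamf1, which encodes the CD150 that was selected for, was at 6.01 ± 2.16 and 9.77 ± 2.01 FPKM, and Ly6a, which encodes Sca-1, at 93.0 ± 11.6 and 142 ± 23.1 FPKM, with adjusted p-values of 0.017 and 0.00349. Kit, which encodes the receptor of the gate, was at 101 ± 17.7 and 107 ± 22.9 FPKM and did not pass (log2 change 0.07, adjusted p 0.761 in limma). With equal medians the calls of Slamf1 and Ly6a were lost and Kit turned to -0.19. The call of Slamf1 was also lost with quantile normalization, in libraries with Xist alone and with a term for Y-linked transcripts.

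Lipid and sugar metabolism moved little as groups. Of 26 cholesterol and SREBP genes 3 rose and 6 fell (1 and 3 in libraries with Xist alone). Fasn, the fatty acid synthase gene, had a log2 change of -0.69 and Scd2, a fatty acid desaturase gene, of -0.96. The relative score of this list differed by -0.27 (exact permutation p 0.0159, adjusted 0.021), and with equal-median scaling 12 members fell. Of 26 glycolysis and hypoxia genes 7 rose and 6 fell (8 and 6 adjusted over the list alone). Without Tunicamycin replicate 1, 11 of them rose, and without Tunicamycin replicate 2, 4 rose. The glycolysis enzyme gene Tpi1 was at 287 ± 13.8 and 156 ± 11.6 FPKM. The lysosomal membrane gene Lamp2 rose in the same libraries, from 50.2 ± 1.35 to 95.9 ± 6.74 FPKM.

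Among genes of at least 100 mean FPKM, 138 rose and 286 fell, with a median log2 change of -0.39, while among genes of 2 to 5 mean FPKM 1053 rose and 299 fell, with a median of 0.25.

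The tests of other splits of the libraries were chosen after the results were seen. Of 100 splits of the 10 libraries into 5 and 5, out of 126 possible, 1 gave as many changed genes as the real one, namely the real split with 6664. The highest other split gave 1812, so a random split is an unlikely source of that count. The other splits mix treated and DMSO libraries, which adds the group difference to their spread. They cannot separate the treatment from other differences that follow the groups. For the list test with a preset correlation, 9 of 100 splits called as many lists as the real 24, and the highest other called 27, so for this count chance cannot be excluded.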
